A study of Homo sapiens with 35 samples.

How the data were processed

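Poly(A) RNA of H9 human embryonic stem cells was sequenced in 35 libraries that form 25 groups. Per the labels' protocols, the cells were kept in E8 medium on Matrigel, passaged with EDTA and seeded as single cells. They were sampled at seeding (t0) and then every 6 h up to 48 h in one of 3 media: E8, the pluripotency control; E6, the control for spontaneous differentiation; and E6 with BMP4 and Activin A at 40 ng/mL each (BA), which drives mesendoderm formation. RNA was extracted with the Nucleospin kit and libraries were made with the Illumina TruSeq mRNA kit, per the labels' protocols, which do not state whether that kit or the counting kept the strand. The 3 t0 libraries, 12 BA, 10 E6 and 10 E8 libraries include 3 replicates at t0, at 24 and 48 h in BA and at 48 h in E6 and in E8. The other 20 groups hold 1 library each. The labels do not say whether replicates were separate cultures.

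The deposited count table holds whole read counts of 58581 genes in each library, under symbols of GENCODE release 23 per the file headers. The submitters' processing notes name alignment to hg38, counting with featureCounts and testing with DESeq2, and give no versions. A second deposited table holds, per the file headers, a log2 fold change, a p-value and an adjusted p-value from the authors' DESeq2 test for 55889 genes in BA at 24 h, BA at 48 h, E6 at 48 h and E8 at 48 h. Its header does not name the reference group. Its log2 fold changes correlated across genes with those computed here against t0, with Pearson's r between 0.905 (BA at 24 h) and 0.963 (BA at 48 h), so t0 was taken as the reference. At an adjusted p below 0.05 the authors' table holds 904 genes for BA at 24 h, 1952 for BA at 48 h, 2150 for E6 at 48 h and 779 for E8 at 48 h. Gene types, lengths and positions came from GENCODE release 29 on GRCh38, which gave a length for 81.3% of the tested genes. The older symbol T is printed as TBXT.

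Library totals were 11793453 to 37191969 counts, which limits the precision of low values: genes with under about 1 CPM (counts scaled to a common total) rest on few reads. CPM values use TMM factors, and each mean is given with its SD over 3 replicates. Genes were tested with the edgeR quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) after TMM normalization and the filter filterByExpr. One model of group, without a replicate block, covered the 15 libraries of the 5 replicated groups and tested 21554 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and calls with a log2 change of at least 1 were also counted. The 5 main comparisons were BA at 24 h with t0, BA at 48 h with BA at 24 h, BA at 48 h with E6 at 48 h, E6 at 48 h with E8 at 48 h, and E8 at 48 h with t0. The 3 secondary comparisons set BA at 48 h and E6 at 48 h against t0 and BA at 48 h against E8 at 48 h, for counts and 11 marker genes only. Time courses of E6 with E8 (20 libraries) and of BA with E6 (22 libraries) were fitted in edgeR with a natural spline of time with 3 degrees of freedom in each medium. Their F-test covered the medium term and its interactions with time, and their direction is the sign of the fitted difference averaged over the 8 time points. The time course filter at first took the number of libraries per medium as the smallest group. It was set to the planned 3 after the first counts had been seen.

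Gene lists of markers and pathway targets, 20 in number, were tested with camera at a preset correlation between genes of 0.01, adjusted over the 100 tests of 20 lists in 5 comparisons. The lists are primed pluripotency, primitive streak and mesendoderm, definitive endoderm, early mesoderm, trophoblast and amnion, neuroectoderm, neural crest, blood and endothelium, fibroblast, BMP-SMAD targets, Activin-Nodal targets, WNT targets, FGF-ERK targets, epithelial, mesenchymal and EMT, HOX, proliferation, p53 and stress, hypoxia and glycolysis, and cholesterol synthesis. Of the HOX list, 1 gene passed the filter, HOXD1. Camera then sets the statistic of that gene against those of the other genes, which is not a test of HOXD1 by itself. Genes were also sorted into classes by their calls. Transient genes were higher at 24 h in BA than at t0 and lower at 48 h than at 24 h. Sustained genes were higher than t0 at 24 and 48 h, with no fall between them. Late genes were higher at 48 h than at 24 h and than at t0, with no call at 24 h. Opposite genes moved in opposite directions from t0 in BA and in E6 at 48 h and also differed between them. The onset of a gene in BA is the first time point with at least 5 CPM and at least 4 times the t0 mean, after adding 1 CPM to both, that also held at the next time point. Most onset values rest on 1 library per time point and have no test.

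The lists, tests, comparisons and the rule for named genes were fixed before the data were examined. The rule names the 11 marker genes in every comparison and, per main comparison, the 6 called genes with the largest rise and the 6 with the largest fall that reach 10 CPM in the higher group, do not overlap between groups and carry a gene name. It adds up to 4 called members of each list with the smallest adjusted p, 2 called members against the list's majority, the 5 transient, late and opposite genes with the largest change, and 5 genes per direction in each time course. Genes named outside that rule are said to be so where they appear.

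Replicate numbers were checked for pairing by the correlation of deviations from the group means. All 30 pairs of libraries with the same number from different groups correlated, with r from 0.573 to 0.871, so the numbers were taken to pair the libraries. The pairing reflects 2 sets of libraries. Number 2 also correlated with number 3 (r from 0.553 to 0.726 over 20 pairs), while number 1 went against both (r from -0.810 to -0.639 over 40 pairs). The 3 deviations of a gene in a group sum to 0. The negative values therefore follow from the positive ones and are no further evidence. The replicate 1 and single libraries (25, with 11793453 to 22115047 counts) have 0.393 to 0.544% of counts on processed pseudogenes. The replicate 2 and 3 libraries (10, with 26097462 to 37191969 counts) have 1.90 to 2.13%. Principal components were taken over the 1000 most variable genes after adding 1 CPM. The fit with the replicate number as a block is given beside a result wherever it changed a call or moved a count by over 1.5 times.

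The steps were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. For BA at 48 h against E6 at 48 h without the block (21060 genes), 10 of 100 genes changed by 2-fold and 44 of 100 changed by 4-fold were recovered, with 0 false calls among 54. With the block, 71 and 93 were recovered, with 7 false calls among 171. This simulation gave each gene the same difference between replicate numbers in every group, as the block assumes. In the real libraries the difference of BA from E6 at 48 h varied between the sets, for SOX2 by 5.64 on the log2 scale. The false calls with the block therefore do not describe the real counts with the block. For the time course of E6 with E8 (18771 genes), with a shift growing over time, 27 and 90 were recovered, with 3 false calls among 120. For BA with E6 (19352 genes), 22 and 81 were recovered, with 4 false calls among 107. The time course counts were simulated without the difference between the library sets that the real libraries have. Their false calls therefore do not describe the real time courses.

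Alternatives were DESeq2 size factors in place of TMM, no filter on low counts, a filter of at least 10 CPM in 3 libraries, the replicate block, each library left out in turn, the DESeq2 1.42.0 Wald test, fits of the 2 groups alone, an estimated correlation in camera, the fry test, splines with 4 degrees of freedom, time as a factor, the DESeq2 likelihood ratio test, and time courses of replicate 1 alone. A fit of replicates 2 and 3 only, a block with 2 levels for the library sets, and fits without single libraries that stood apart were added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.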

Results

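Human embryonic stem cells of the H9 line were followed by RNA sequencing for 48 h in 3 media, and the comparisons ask which genes mark the path from pluripotency to mesendoderm, the common precursor of mesoderm and endoderm. BA medium carries BMP4 and Activin A, which drive that path, and E6 carries neither. E8 keeps the cells pluripotent. The 35 libraries hold 11793453 to 37191969 counts each. Libraries differed most along an axis that separates replicate 1 and the single libraries (25 libraries) from replicates 2 and 3 (10 libraries): it holds 59.8% of the variance of the 1000 most variable genes, against 24.5% for the axis of time in BA. Within a group, replicates 2 and 3 correlated at r = 0.987 to 0.99 across genes on the log scale, and replicate 1 with either at 0.868 to 0.908. Genes are not independent replicates, so these values describe the libraries only. The split runs through every replicated group and is not a difference between media, but it widens the SD of many genes below. Levels are mean CPM ± SD over 3 replicates (n = 3) unless a single library is named, and adjusted p-values come from edgeR's quasi-likelihood test.

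**Figure D1:**
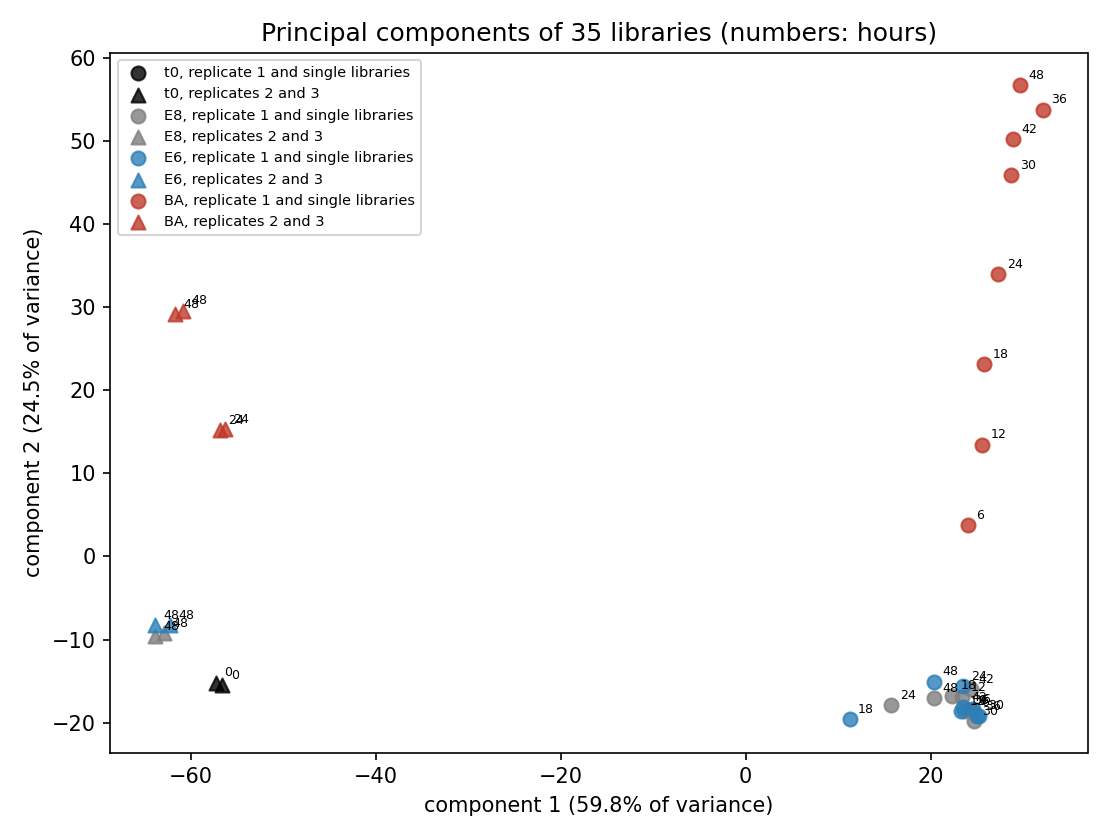
First (horizontal, 59.8% of variance) and second (vertical, 24.5%) principal component of the 1000 most variable genes, 1 point per library, coloured by medium and numbered by hours. Circles are replicate 1 and single libraries and triangles are replicates 2 and 3, which lie apart along the first component.

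After 24 h in BA, primitive streak genes had risen from near absence, and targets of BMP signalling with them. TBXT, the brachyury transcription factor of the streak (chromosome 6, 166157656 to 166168700 on GRCh38), stood at 36.5 ± 52.3 CPM in BA and 0.151 ± 0.103 CPM at t0, a 238-fold rise (log2 change 7.90 ± 1.30 SE, adjusted p = 0.0108). EOMES, the T-box factor needed for endoderm (chromosome 3, 27715949 to 27722711), rose from 0.174 ± 0.0444 to 176 ± 236 CPM (adjusted p = 0.0342). Their SDs exceed the means since EOMES stood at 449 CPM in replicate 1 and at 38.3 and 42.4 CPM in replicates 2 and 3. The WNT ligand gene WNT3, which starts streak formation in the embryo, rose 66.6-fold to 86.9 ± 47.7 CPM (adjusted p = 0.00143). NODAL, the ligand that patterns the streak, rose 16.7-fold to 24.6 ± 1.89 CPM (adjusted p = 0.00298). No E6 or E8 group at 24 h has replicates, so this comparison with t0 cannot part the added factors from time, seeding and culture. In all, 339 of 21554 genes differed, 271 higher and 68 lower in BA, of which 255 and 59 changed by at least 2-fold. With the replicate block the count was 1929, 1255 of them higher, and 114 with only the libraries of the 2 groups. Leaving out any of the 6 libraries lowered it, to between 84 without replicate 3 of t0 and 206 without replicate 3 of BA at 24 h. The call of TBXT was lost without any 1 of the 3 t0 libraries (adjusted p up to 0.0754) and that of EOMES without 5 of the 6 libraries (up to 0.203).

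The remaining marker genes showed no call at 24 h. MIXL1, a homeobox gene of the streak, stood at 146 ± 230 CPM against 0.720 ± 0.0241 CPM at t0 (adjusted p = 0.0775, and 0.0014 with the block). The endoderm factor SOX17 stood at 2.41 ± 4.18 CPM (adjusted p = 0.387, with the block 0.0107), and the caudal homeobox gene CDX2 at 2.02 ± 3.14 CPM (0.133, with the block 0.00677). GSC, the organizer homeobox gene, and MESP1, of nascent mesoderm, stayed below 1 CPM (adjusted p = 0.561 and 0.653). The pluripotency factor POU5F1 measured 2060 ± 1105 CPM in BA and 957 ± 465 CPM at t0 (adjusted p = 0.797, with the block 0.0386). SOX2, shared by pluripotent and neural cells, measured 143 ± 63.9 and 216 ± 10.2 CPM (adjusted p = 1), and NANOG, a pluripotency homeobox gene, 81.5 ± 33.6 and 46.9 ± 17.4 CPM (0.902). POU5F1 and NANOG have near-identical pseudogene copies that the counting could split, so their levels are uncertain. The eye and neural factor PAX6 stayed below 1 CPM in both groups (adjusted p = 0.967).

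Among the called genes with 10 CPM or more, the long noncoding RNA PCAT14, first known from prostate cancer, rose furthest, from 1.29 ± 0.253 to 1490 ± 1451 CPM (log2 change 10.15 ± 0.83 SE, adjusted p = 1.15e-04). SP5, a zinc finger gene switched on by WNT, rose to 38.6 ± 49.6 CPM (9.83 ± 1.54, adjusted p = 0.0078; up to 0.0648 when a t0 library was left out). SAMD11, a SAM domain gene, reached 69.8 ± 25.4 CPM (8.86 ± 0.67), TFAP2A, a factor of amnion and surface ectoderm, 50.4 ± 48.0 CPM (8.83 ± 0.80), and MSX2, a homeobox target of BMP, 93.7 ± 52.2 CPM (8.49 ± 0.50, adjusted p = 8.04e-06). The calls of PCAT14, SAMD11, TFAP2A and MSX2 held whichever library was left out. The serotonin receptor gene HTR1A fell by 5.24 on the log2 scale, from 19.3 ± 8.71 to 0.489 ± 0.193 CPM (adjusted p = 0.00731). C6orf141, a gene of unknown function, fell by 3.05 ± 0.49, from 12.1 ± 1.06 CPM (0.00931). The actin regulator LIMCH1, the homeobox gene IRX2 and the antisense RNA JAKMIP2-AS1 also fell, with adjusted p = 0.0438, 0.0224 and 0.0186, and each lost its call without at least 4 of the 6 libraries. Whether the counting kept the strand is not stated, and if it did not, JAKMIP2-AS1 cannot be told from its sense partner.

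Of the signalling lists, BMP-SMAD targets moved most. Of 13 tested, 9 rose and 0 fell (13 rose adjusted over the list alone), and the list stood above other genes (camera adjusted p = 1.02e-36; 2.72e-04 with an estimated correlation). BAMBI, a decoy receptor that dampens BMP signals, rose 14.4-fold to 277 ± 11.7 CPM (adjusted p = 1.17e-05). SMAD6, an inhibitory SMAD, rose 30.1-fold to 94.9 ± 52.9 CPM, and the BMP antagonist gene NOG rose to 21 ± 22.9 CPM (adjusted p = 0.00326 and 0.0221; NOG up to 0.133, lost without 3 of the 6 libraries). Of 10 Activin-Nodal targets, 2 rose (4 adjusted over the list alone; camera adjusted p = 1.47e-06, and 0.0259 with an estimated correlation): NODAL and SMAD7, the latter 3.36-fold (adjusted p = 0.0262, lost without any 1 of the 6 libraries). Of 12 WNT targets, 3 rose (7 adjusted over the list alone; camera adjusted p = 9.11e-09, and 0.195 with an estimated correlation). They are SP5, the feedback lipase gene NOTUM, at 9.37 ± 9.96 CPM from 0 counts at t0 (adjusted p = 0.00177), and the WNT effector TCF7, which rose to 41.5 ± 25.3 CPM (0.015, up to 0.0959 and lost without 3 of the 6).

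Among the cell identity lists, 5 of 15 streak genes rose and 0 fell (11 adjusted over the list alone; with the block 10), with camera adjusted p = 1.62e-17 and 0.0398 with an estimated correlation. Of 10 trophoblast and amnion genes, 4 rose and 0 fell (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.38e-08, and 0.0154 with an estimated correlation). They are TFAP2A, its relative TFAP2C, at 10.6 ± 1.42 CPM, and the zinc finger factors GATA3, at 96.3 ± 89.0 CPM, and GATA2, at 18.5 ± 10.3 CPM (adjusted p = 0.0399, 0.00173 and 0.00178 for the last 3). TFAP2C lost its call without any 1 of the 6 libraries (up to 0.175). Of 14 early mesoderm genes 0 were called by edgeR (3 rose adjusted over the list alone), while camera placed the list higher (adjusted p = 0.00749, and 0.486 with an estimated correlation). Of 13 neuroectoderm genes 0 were called, and camera placed the list lower (adjusted p = 6.64e-04; 0.0503 with an estimated correlation and 0.0643 without replicate 1 of t0). The HOX list, tested on HOXD1 alone, passed camera (adjusted p = 3.13e-07, and 0.00541 with an estimated correlation), with HOXD1 at 0.762 ± 0.140 CPM and 0 counts at t0 (its call was lost without 2 of the 6 libraries, adjusted p up to 0.0535). The hypoxia and glycolysis list passed at 0.0336 (0.762 with an estimated correlation, 0.145 with the block, and up to 0.260 when 1 library was left out). In it PDK1, a kinase that inhibits pyruvate dehydrogenase, rose 4.20-fold to 257 ± 52.8 CPM (adjusted p = 0.0143, up to 0.0844 and lost without 3 of the 6). Camera did not place 20 pluripotency genes (0.967) or 12 endoderm genes (0.161, with the block 0.0207) apart, although FGF4, a growth factor gene in the first list, rose to 5.33 ± 4.08 CPM (adjusted p = 0.00404). Outside the lists that passed, the matrix protease gene MMP2 rose 4.49-fold (adjusted p = 0.0224, up to 0.193 and lost without 5 of the 6), the only call among 11 mesenchymal genes (camera 0.25, with the block 0.00898). The ERK phosphatase gene DUSP4, the only call among 15 FGF-ERK targets (camera 0.541), fell from 39.8 ± 9.21 to 14.2 ± 4.93 CPM (adjusted p = 0.0413, up to 0.177 and lost without 5 of the 6).

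Between 24 and 48 h in BA the called genes included 2 of 14 early mesoderm genes, DLL3 and BMP4. DLL3, a Notch ligand gene of forming somites, rose from 0.785 ± 0.516 to 34.7 ± 45.5 CPM (log2 change 5.44 ± 0.91 SE, adjusted p = 0.0253). FGF17, a growth factor gene of the streak region, rose from 0.220 ± 0.227 to 11.4 ± 13.6 CPM (5.81 ± 0.98, adjusted p = 0.0255). BMP4, itself one of the added factors (chromosome 14, 53949736 to 53958761), rose 12.8-fold to 112 ± 95.2 CPM (adjusted p = 0.0303). SFRP2, a secreted WNT modulator abundant in pluripotent cells, fell from 956 ± 132 to 245 ± 89.1 CPM, by 1.92 ± 0.25 on the log2 scale (adjusted p = 0.0102). The test called 98 genes, 74 higher and 24 lower at 48 h, 71 and 24 of them by at least 2-fold; with the replicate block the count was 2158, 1362 of them higher. With only the libraries of the 2 groups edgeR called 0 genes (1493 at an unadjusted p below 0.05), so no gene named for this comparison passes there. It ranged from 3 without replicate 3 of BA at 24 h to 175 without replicate 1 of BA at 48 h, and every gene named for this comparison lost its call without replicate 2 or 3 of BA at 24 h (adjusted p up to 0.250, for ATP12A).

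Other genes that rose by this rule were the GABA receptor gene GABBR2, to 14.4 ± 10.6 CPM (adjusted p = 0.0353), the proton pump gene ATP12A, to 70.2 ± 55.0 CPM (0.0443), and GLIPR2, of the Golgi, to 53.2 ± 52.8 CPM (0.0326). GABBR2 changed by 0.64 on the log2 scale in replicate 1 and by 4.97 in replicates 2 and 3. Genes that fell were D21S2088E, a noncoding gene (to 2.11 ± 1.34 from 18.3 ± 0.356 CPM, adjusted p = 0.0206), the Arf exchange factor gene IQSEC2 (to 46.7 ± 25.2 from 249 ± 38.3 CPM, 0.0248), and THY1, a surface glycoprotein gene (to 107 ± 53.1 from 490 ± 138 CPM, 0.0443). The hormone receptor gene MCHR1 and the protease gene MMP9 fell by 1.92 and 1.72 (0.0187 and 0.0176). None of the 11 marker genes was called. SOX17 stood at 64.1 ± 99.6 CPM at 48 h (adjusted p = 0.409, with the block 4.43e-04), MESP1 at 17.1 ± 22.6 CPM (0.13, with the block 0.00779) and GSC at 8.04 ± 12.1 CPM (0.346, with the block 0.00911). SOX2 changed by -3.94 in replicate 1 and by -0.35 in replicates 2 and 3 (log2), so that its mean difference of -0.58 describes neither set. POU5F1, TBXT and MIXL1 had adjusted p = 1, EOMES 0.994, NANOG 0.602, CDX2 0.820 and PAX6 0.859.

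Camera placed the early mesoderm list higher at 48 h (adjusted p = 1.95e-12, and 0.0503 with an estimated correlation), with 2 of 14 genes called, DLL3 and BMP4, and 10 adjusted over the list alone. Endoderm (3.92e-04, estimated 0.27; 4 of 12 rose adjusted over the list alone), mesenchymal (0.00272, estimated 0.319; 4 of 11 likewise) and trophoblast genes (0.00162, estimated 0.125) were also placed higher with 0 members called by edgeR. Without replicate 1 of BA at 48 h, camera gave 0.228 for the endoderm list and 0.452 for the mesenchymal list. Streak genes passed at 0.0409 (estimated 0.659) and changed direction without that library (0.883). The pluripotency list was placed lower (5.06e-04, estimated 0.288, and 0.243 without replicate 1 of BA at 48 h), with SFRP2 as the only call among 20 genes. Activin-Nodal targets were placed lower at 0.0248 (estimated 0.275, with the block 0.131, and up to 0.0731 when a library was left out). The HOX list, HOXD1 alone, was placed lower at 1.1e-04 (estimated 0.0183), with no call of HOXD1 by edgeR. Stress genes (0.0344, estimated 0.598), hypoxia genes (4.5e-04, estimated 0.598) and cholesterol synthesis genes (0.00109, estimated 0.556) were placed higher, and each missed the threshold without at least 1 of the 6 libraries (up to 0.280, 0.0865 and 0.0910). The estimated values are camera's adjusted p with an estimated correlation.

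**Figure D2:**
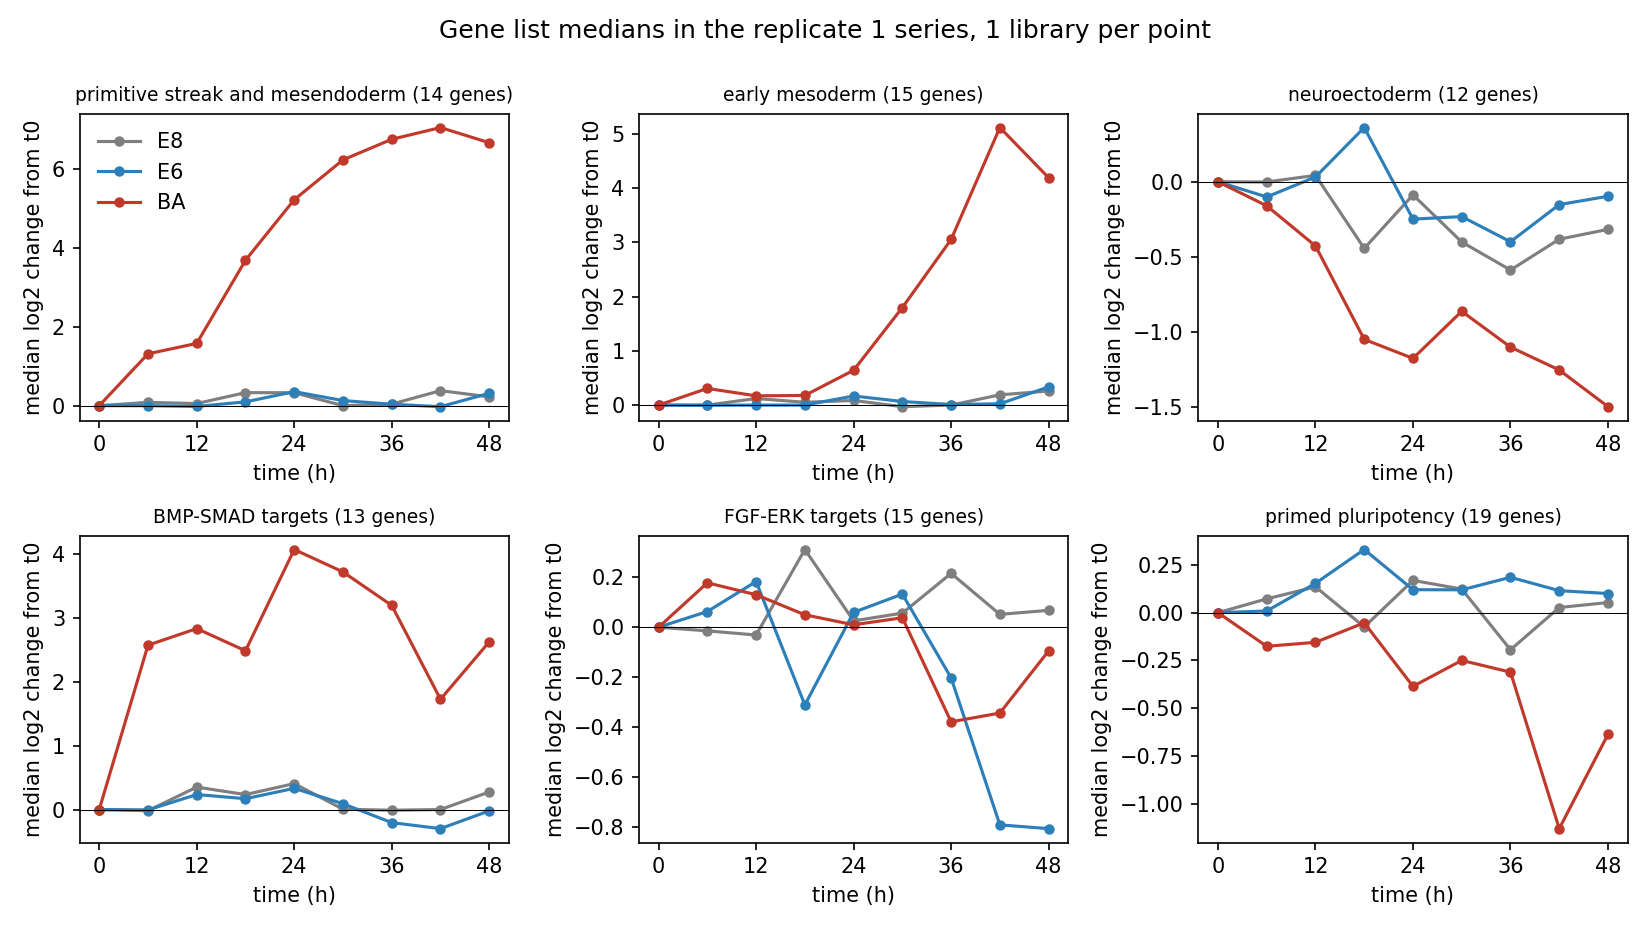
Median log2 change from t0 (vertical) of 6 gene lists against time in hours (horizontal) in the replicate 1 series, 1 library per point, with red for BA, blue for E6 and grey for E8. In BA the streak median reaches 5.22 at 24 h, when the early mesoderm median is 0.64, and the mesoderm median reaches 4.19 at 48 h.

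BA against E6 at 48 h sets the added factors against the same medium without them. BAMBI stood at 316 ± 30.0 CPM in BA and 9.72 ± 0.324 CPM in E6, a 33.2-fold difference (log2 change 5.05 ± 0.27 SE, adjusted p = 3.75e-06). FN1, the fibronectin gene of migrating mesoderm, was 18.7-fold higher in BA, at 2428 ± 1071 CPM (adjusted p = 0.00809, up to 0.0637 and lost without 2 of the 6 libraries). FEZF1, a forebrain zinc finger gene (chromosome 7, 122301394 to 122310691), was at 0.446 ± 0.152 CPM in BA and 35.7 ± 7.76 CPM in E6 (log2 change -6.26 ± 0.49 SE, adjusted p = 7.64e-05). NPTX1, which encodes a pentraxin of neurons, was at 0.539 ± 0.499 CPM in BA and 103 ± 100 CPM in E6 (-7.59 ± 1.11, adjusted p = 0.00302). The test called 759 genes, 437 higher and 322 lower in BA, with 390 and 284 of them by at least 2-fold, and 4760 with the replicate block, 2665 of them higher, against 76 with only the libraries of the 2 groups. Leaving out 1 library gave from 257 genes without replicate 3 of E6 to 670 without replicate 1 of BA.

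Of the marker genes, TBXT was 51.5-fold higher in BA (47.1 ± 38.2 against 0.926 ± 0.118 CPM, adjusted p = 0.0164). EOMES stood at 368 ± 562 CPM in BA and 0.938 ± 1.28 CPM in E6 (adjusted p = 0.0251), MIXL1 at 257 ± 385 and 1.0 ± 1.18 CPM (0.0383), and MESP1 at 17.1 ± 22.6 and 0.293 ± 0.184 CPM (0.0400). SOX17 stood at 64.1 ± 99.6 CPM in BA, with 1 library of E6 above 0 counts (adjusted p = 0.0494). Each of these 5 calls was lost without at least 3 of the 6 libraries, with adjusted p up to 0.0980 for TBXT, 0.137 for EOMES, 0.177 for MIXL1, 0.171 for MESP1 and 0.212 for SOX17. GSC missed the threshold (adjusted p = 0.0602, with the block 0.0012), as did CDX2 (0.139, with the block 0.00633). SOX2 was at 93.2 ± 78.8 CPM in BA and 334 ± 68.0 CPM in E6 (adjusted p = 0.332). In BA it was at 3.60 CPM in replicate 1 and at 152 and 124 CPM in replicates 2 and 3. NANOG (adjusted p = 0.374) was lower in BA in replicate 1 and higher in replicates 2 and 3, by -1.32 and 1.89 on the log2 scale. POU5F1 (0.732) and PAX6 (0.898) were not called.

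Among the genes that differed most were the homeobox genes EVX1, of the posterior streak, at 48.8 ± 73.5 CPM, and ISL1, of cardiac progenitors and amnion, at 19.2 ± 31.9 CPM, each with 1 library of E6 above 0 counts (adjusted p = 0.0424 and 0.0499). GATA6-AS1, antisense to the endoderm factor gene GATA6, was at 18.2 ± 27.6 CPM with 0 counts in E6 (0.0434); its reads may include those of its partner. All 3 lost the call without at least 4 of the 6 libraries (adjusted p up to 0.187, 0.213 and 0.144). PCAT14 was at 1044 ± 355 CPM against 2.22 ± 1.58 CPM (1.83e-04). Lower in BA were the forebrain homeobox gene LHX5, at 17.6 ± 14 CPM in E6 (adjusted p = 0.0229, up to 0.0935 when a library was left out), and HES3, a repressor of neural differentiation, at 35.2 ± 12.3 CPM (0.00607). FEZF1-AS1, which overlaps FEZF1 on the other strand and may share its reads, was lower too (0.00133), as was JAKMIP2-AS1 (0.00345).

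By list, 8 of 15 streak genes were higher in BA and 0 lower (14 adjusted over the list alone and 14 with the block; camera adjusted p = 8.6e-15, and 0.0529 with an estimated correlation). Of 14 early mesoderm genes, 5 were higher and 0 lower (11 adjusted over the list alone; camera 2.26e-09, and 0.0897 with an estimated correlation). They include KDR, a receptor of cardiovascular progenitors, 4.88-fold higher at 235 ± 118 CPM (adjusted p = 0.00296), BMP4, 20.4-fold higher (0.00355), and the heart and amnion factor HAND1, at 94.3 ± 145 CPM (0.0328, up to 0.161 and lost without 3 of the 6). Of 10 trophoblast and amnion genes, 6 were higher and 0 lower (7 and 1 adjusted over the list alone; camera 3.39e-09, and 0.00624 with an estimated correlation), among them TFAP2A at 42.2 ± 13.2 CPM and GATA3 at 82.3 ± 45.4 CPM against 0.114 ± 0.0294 and 0.207 ± 0.164 CPM (2.02e-04 and 0.00101). Of 13 neuroectoderm genes, 1 was lower, the pituitary and forebrain factor HESX1 (0.584 ± 0.404 against 9.24 ± 4.05 CPM, adjusted p = 0.0211, up to 0.0683 and lost without 4 of the 6), with 3 adjusted over the list alone and 8 with the block (camera 1.1e-04, and 0.0259 with an estimated correlation). BMP-SMAD targets held 5 higher of 13 (12 adjusted over the list alone; camera 2.34e-23, and 2.72e-04 with an estimated correlation). Activin-Nodal targets held 3 of 10 (6 adjusted over the list alone; camera 7.4e-09, and 0.0048 with an estimated correlation), of which GDF3, a TGF-beta ligand gene of pluripotent cells, changed by -0.57 in replicate 1 and by 5.53 in replicates 2 and 3 (its call was lost without 5 of the 6 libraries, up to 0.111). WNT targets held 3 of 12 (7 adjusted over the list alone; camera 1.92e-05, and 0.303 with an estimated correlation), FGF-ERK targets 1 of 15 (3 adjusted over the list alone; camera 0.037, 0.399 with an estimated correlation and 0.0938 with the block) and mesenchymal genes 2 of 11 (3 adjusted over the list alone; camera 1.93e-04, and 0.251 with an estimated correlation). The 1 FGF-ERK call was the ETS factor gene ETV5, 2.21-fold higher in BA (adjusted p = 0.00343). Without replicate 1 of either group camera no longer placed the FGF-ERK list apart (0.364 without that of BA and 0.214 without that of E6), and over the time course ETV5 was lower in BA. Cholesterol synthesis genes passed with the block only (camera 0.0269, 0.25 without it). Of 12 endoderm genes 2 were higher (5 higher and 1 lower adjusted over the list alone; camera 0.0719, with the block 4.46e-04): SOX17 and GATA4, the latter at 44.0 ± 73.3 CPM (adjusted p = 0.0333, up to 0.164 and lost without 4 of the 6; DESeq2 gave it no adjusted p).

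Medium E6 lacks growth factors that E8 supplies, FGF2 and TGF-beta among them, and after 48 h the cells in E6 had lower targets of FGF signalling. DUSP6, a phosphatase gene switched on by ERK (chromosome 12, 89347232 to 89353271), was at 52.6 ± 21.9 CPM in E6 and 496 ± 45.5 CPM in E8 (log2 change -3.26 ± 0.49 SE, adjusted p = 0.0256). The ETS factor genes ETV5 and ETV4, also targets of ERK, were at 24.6 ± 3.56 against 88.6 ± 4.98 CPM and at 58.4 ± 9.81 against 170 ± 14.2 CPM (adjusted p = 0.00172 and 0.0154). FEZF1 was 103-fold higher in E6, at 35.7 ± 7.76 CPM (log2 change 6.69 ± 0.50 SE, adjusted p = 2.32e-04). The test called 31 genes, 19 higher and 12 lower in E6, 18 and 10 of them by at least 2-fold, and 612 with the replicate block, 328 of them higher. With only the libraries of the 2 groups edgeR called 0 (946 at an unadjusted p below 0.05). Leaving out 1 library gave from 2 genes without replicate 2 of E8 to 56 without replicate 1 of E6. Of the 12 genes named for this comparison, FEZF1 and ETV5 kept the call whichever library was left out, and DUSP6 lost it without 5 of the 6 (adjusted p up to 0.228).

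FEZF1-AS1 was also higher in E6, with FEZF1 on the other strand (31.4 ± 18.5 against 0.507 ± 0.299 CPM, adjusted p = 0.0124). PAPLN, of the extracellular matrix, was at 49.4 ± 22.1 against 5.81 ± 2.10 CPM (0.0112), the cation channel gene TRPC4 at 32.2 ± 4.13 against 4.91 ± 0.867 CPM (0.00608), and the neuropeptide receptor gene VIPR2 at 12.6 ± 2.54 against 2.20 ± 0.162 CPM (0.0117). C5orf38, which neighbours IRX2 and may share reads with it, passed narrowly (adjusted p = 0.0499, up to 0.303 when a library was left out). Lower in E6 were HMX2, a homeobox gene (3.42 ± 1.37 against 22.6 ± 4.39 CPM), the cathepsin gene CTSK (11.7 ± 5.11 against 59.1 ± 5.83 CPM) and the tight junction gene CLDN11 (5.71 ± 0.743 against 22.3 ± 1.03 CPM), with adjusted p = 0.00929, 0.00929 and 0.0112. None of the 11 marker genes was called. POU5F1 was at 844 ± 252 CPM in E6 and 1330 ± 614 CPM in E8 (adjusted p = 1), SOX2 at 334 ± 68.0 and 161 ± 49.3 CPM (1) and NANOG at 16.4 ± 5.63 and 52.4 ± 17.3 CPM (0.718).

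The FGF-ERK list held 3 lower and 0 higher genes of 15 (5 lower adjusted over the list alone, 6 with the block; camera adjusted p = 4.35e-14, and 0.00541 with an estimated correlation). Activin-Nodal targets were placed lower with 0 of 10 called by edgeR (1 lower adjusted over the list alone; camera 3.13e-07, and 0.016 with an estimated correlation). Neuroectoderm genes were placed higher with 0 of 13 called (1 adjusted over the list alone; camera 0.0344, 0.224 with an estimated correlation and 0.666 without replicate 1 of E6). The other 17 lists held 0 called genes and did not pass camera, including pluripotency (0.703) and BMP-SMAD targets (0.82); 3 passed with the block, trophoblast (0.0492), stress (0.0424) and cholesterol synthesis genes (0.00591).

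Cells kept in E8 for 48 h differed from t0 in 30 of 21554 genes without the replicate block and in 5510 with it. This comparison shows what time, seeding and culture change in E8. SLC16A3, the lactate exporter gene (chromosome 17, 82228397 to 82261129), rose from 1.86 ± 0.567 to 140 ± 62.4 CPM (log2 change 6.26 ± 0.98 SE, adjusted p = 0.0456). PLOD2, a collagen-modifying enzyme gene induced by low oxygen, rose from 20.8 ± 10.4 to 116 ± 11.7 CPM (2.49 ± 0.31, adjusted p = 0.0147). NQO1, an oxidative stress enzyme gene, fell from 149 ± 46.0 to 41.9 ± 6.16 CPM (-1.81 ± 0.30, adjusted p = 0.0466). The coregulator gene PNRC1 (0.0147), the kinase inhibitor PIK3IP1 and ABTB1, of the ankyrin repeat family (0.0466 both), rose. The test called 30 genes, 29 higher and 1 lower, of which 28 and 1 changed by at least 2-fold, and 5510 with the replicate block, 2716 of them higher. With only the libraries of the 2 groups edgeR called 0 (2482 at an unadjusted p below 0.05). Leaving out 1 library gave from 0 genes without replicate 2 of t0 to 624 without replicate 1 of E8, and every named gene lost its call without at least 4 of the 6 libraries (adjusted p up to 0.268). At an unadjusted p below 0.05, with all libraries, 3226 genes passed.

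No marker gene was called in E8, with POU5F1 at 1330 ± 614 CPM (adjusted p = 0.857), SOX2 at 161 ± 49.3 CPM (0.914) and NANOG at 52.4 ± 17.3 CPM (0.961). Of 13 hypoxia and glycolysis genes, 0 were called by edgeR over all genes, while 9 rose adjusted over the list alone and 10 with the block (camera adjusted p = 1.05e-09, and 0.275 with an estimated correlation). The glucose transporter gene SLC2A1 measured 2158 ± 880 CPM against 473 ± 14.4 CPM at t0, and BNIP3, of mitophagy, 333 ± 143 against 30.9 ± 8.14 CPM; these list members were chosen after their values were seen. Camera also placed the pluripotency list lower (0.0291, 0.575 with an estimated correlation, 0.0938 with the block, and 0.137 without replicate 3 of E8) and early mesoderm genes higher (0.037, 0.598 with an estimated correlation, 0.0553 with the block, and up to 0.0756 when a library was left out). No member of either was called, nor of any other list.

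In 5 lists camera passed none of the main comparisons: neural crest, blood and endothelium, fibroblast, epithelial and proliferation. With the block the fibroblast list was placed higher in BA at 24 h than at t0 (0.0424). Their called members were RUNX1, a blood factor gene, at 11.8 ± 6.83 CPM in BA at 48 h against 1.34 ± 0.385 CPM in E6 (adjusted p = 0.04, lost without any 1 of the 6 libraries), the keratin gene KRT8, 3.41-fold higher in the same comparison (0.0335, lost without 5 of the 6), and THY1 between 24 and 48 h in BA. None of the 14 proliferation genes was called in any of the 5, and none of the 7 neural crest genes.

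Against t0, 1373 genes differed after 48 h in BA (990 higher and 383 lower; 6153 with the replicate block) and 836 after 48 h in E6 (582 and 254; 7553 with the block). BA at 48 h differed from E8 at 48 h in 526 genes (325 higher and 201 lower; 3801 with the block). In BA against t0 the called markers were TBXT (log2 change 8.33 ± 1.32 SE, adjusted p = 0.00416), EOMES (11.02 ± 2.13, 0.011), MIXL1 (8.50 ± 1.95, 0.0237), GSC (6.62 ± 1.61, 0.0304), MESP1 (8.01 ± 1.58, 0.0119) and SOX17 (0.0353). TBXT kept the call whichever library was left out, and the other 5 lost it without replicate 2 or 3 of t0 (adjusted p up to 0.169). SOX2 (-1.15, adjusted p = 0.536), POU5F1 (0.751) and NANOG (0.929) were not called, nor was CDX2 (0.153, with the block 0.00889). Against E8 at 48 h, TBXT (0.011), EOMES (0.0348), GSC (0.0492) and MESP1 (0.0309) were higher, TBXT losing the call without 2 of the 6 libraries (up to 0.0835) and the others without 4 (up to 0.168, 0.210 and 0.141), and MIXL1 (0.0569, with the block 3.12e-04), SOX17 (0.0729, with the block 3.51e-05) and CDX2 (0.333, with the block 0.0216) passed with the block only. E6 against t0 called no marker; NANOG (-1.52, adjusted p = 0.185, with the block 0.0475) and TBXT (2.65, 0.217, with the block 0.0339) passed with the block only. Leaving out 1 library gave 376 to 1443 genes for BA against t0, 48 to 1575 for E6 against t0 and 193 to 504 for BA against E8; the lowest counts were those without replicate 3 of t0 or replicate 2 of E8, and the highest those without replicate 1 of BA or of E6.

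By class, 215 genes were called higher than t0 at 24 and 48 h in BA with no call down between them, 58 were called higher at 48 h than at t0 and at 24 h with no call at 24 h, and 8 rose and fell back. A missing call at 24 h does not exclude an earlier rise. The transient, sustained and late classes compare BA with t0, so they can also hold changes of time, seeding and culture. Of the sustained genes, SLC16A3, PLOD2, PNRC1 and PIK3IP1 were also called higher in E8 at 48 h than at t0. Transient genes included CBLN1, a synapse organizer gene, which rose from 3.96 ± 0.952 to 96.4 ± 19.3 CPM at 24 h (log2 change 4.61 ± 0.24 SE, adjusted p = 3.13e-06), MMP9, which rose to 20.5 ± 1.5 CPM (adjusted p = 0.00143) before its fall, IQSEC2 and MCHR1. At 24 h the calls of IQSEC2 and MCHR1 were lost without 5 and 3 of the 6 libraries (adjusted p up to 0.105 and 0.0648). POTEE, of a family of near-identical genes, was called transient from replicates 2 and 3 alone, where it stood at 229 CPM in both at 24 h against 0.0532 CPM in replicate 1, and the counting could split reads between it and its paralogs (lost without 3 of the 6, up to 0.121). Among late genes the 5 with the largest rise are FGF17, DLL3, GABBR2, ATP12A and BMP4. In 6 genes BA and E6 moved opposite ways from t0: PAPLN was at 1.17 ± 0.279 CPM in BA and 49.4 ± 22.1 CPM in E6 (adjusted p = 1.03e-04), while the scaffold gene MPP1 and the cytoskeletal gene TES were 5.66-fold and 4.06-fold higher in BA (0.00148 and 2.74e-04). BAMBI belongs to the same class. The comparisons share libraries. Lists of these sizes drawn independently would share 0.302 transient, 12.4 sustained, 3.40 late and 22 opposite genes. The sustained, late and opposite values leave out 1 condition of the class: no fall, no call at 24 h and the direct difference. The 6 opposite genes lie below their value. In 10 simulations of unchanged groups each class held 0 genes. Unchanged groups give few calls, so classes that need several calls are nearly empty in advance. The simulations therefore set no chance value for groups that do differ. Part of any excess in the other classes may come from the shared libraries. With the replicate block the classes held 137 transient, 977 sustained, 909 late and 209 opposite genes. When 1 library was left out they held 1 to 11, 49 to 289, 1 to 112 and 1 to 22.

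Over the time course, EOMES and MIXL1 came on first in BA, at 6 h, followed by TBXT at 18 h and by GSC, SOX17 and MESP1 at 30 h. These times follow the onset rule, rest on 1 library at most time points and have no test. EOMES stood at 7.61 CPM at 6 h, 36.9 at 12 h, 183 at 18 h and 1162 at 42 h. TBXT stood at 1.89 CPM at 12 h, 19.0 at 18 h and 354 at 42 h, and SOX17 reached 49.3 CPM at 30 h. With replicate 1 alone at 24 h, SOX17 came on at 24 h. In E6 and in E8 none of these genes met the rule, nor did POU5F1, SOX2, NANOG, CDX2 or PAX6 in any medium. Other list members, picked after their onsets were seen, fall along the same course: WNT3 and GATA3 at 6 h, the apelin receptor gene APLNR and the WNT antagonist gene DKK1 at 12 h, NODAL and the endoderm factor GATA6 at 18 h, the homeobox gene LHX1 and HAND1 at 30 h, and TBX6, of presomitic mesoderm, at 36 h.

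**Figure D3:**
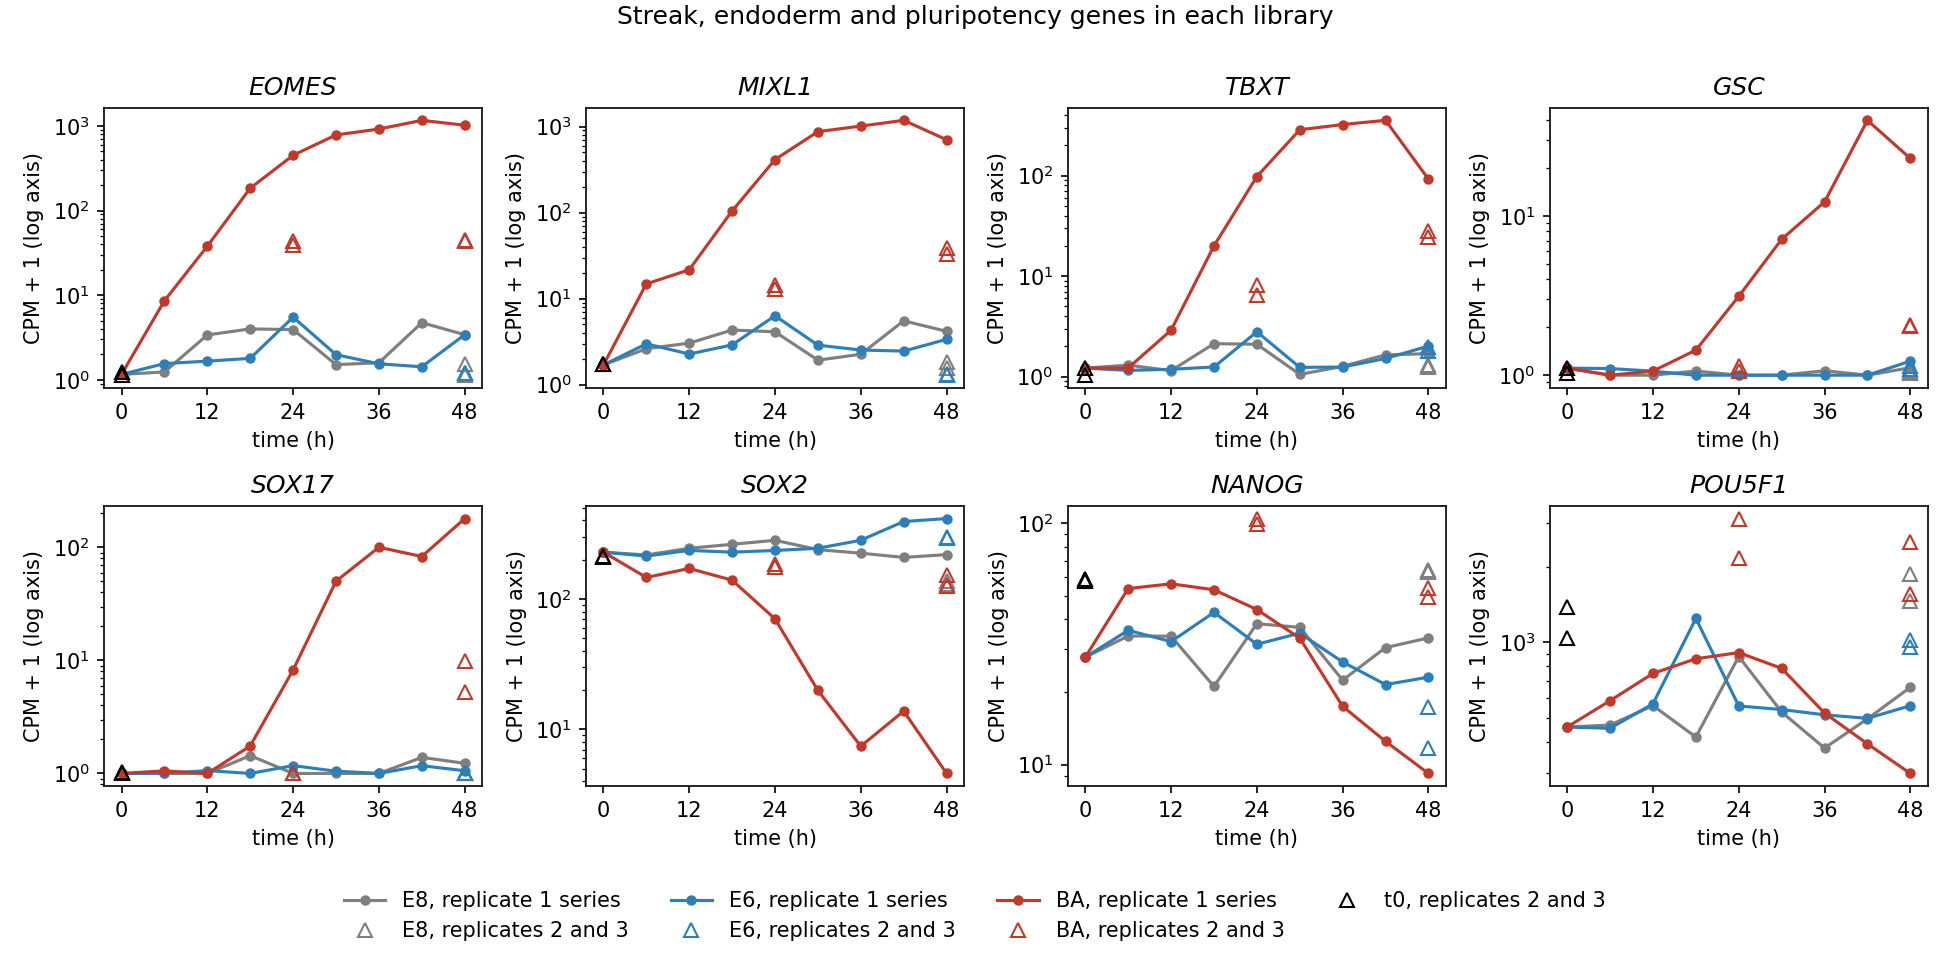
CPM plus 1 on a log axis (vertical) of 8 marker genes against time in hours (horizontal), with red for BA, blue for E6, grey for E8 and black for t0. Filled points joined by lines are the replicate 1 series and open triangles are replicates 2 and 3, in which EOMES at 48 h in BA stands at 42.3 and 44.3 CPM against 1017 CPM in replicate 1.

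The spline test of BA against E6 over 6 to 48 h called 2451 of 19902 genes, 1308 higher and 1143 lower in BA. With replicate 1 alone at the replicated time points it called 5129, of which 2268 were shared. The fit had no term for the library sets. At 24 h BA held libraries of replicates 2 and 3 and E6 held none of them. Calls with all libraries can therefore include differences between the sets. HES3 and HTR1A were lower in BA throughout (mean log2 difference -5.64 and -5.26, adjusted p = 8.37e-08 and 1.30e-06), as were JAKMIP2-AS1 (-4.15), the anterior hindbrain homeobox gene GBX2 (-3.70, 7.53e-04) and IDO1, an enzyme gene of tryptophan breakdown (-3.66, 0.0140). SAMD11 (7.92, 4.83e-08), PCAT14 (7.91, 9.53e-07), GATA6 (8.64, 0.00173), HAND1 (8.01, 3.83e-04) and EVX1 (9.37e-04) were highest above E6. Here SOX2 was lower in BA (-2.17, adjusted p = 0.00588), from 145 CPM at 6 h to 6.44 CPM at 36 h, both in single libraries. At 48 h its mean in BA over 3 replicates was 93.2 CPM, against 3.60 CPM in replicate 1 alone. Of the other markers, TBXT, EOMES, MIXL1, GSC, SOX17, MESP1 and CDX2 were higher (adjusted p = 5.93e-05, 1.59e-04, 5.32e-04, 0.00820, 0.00344, 0.00102 and 0.00929). POU5F1 (0.726) and PAX6 (0.696) were not called. NANOG was not called with all libraries (0.44, adjusted p = 0.243) but was with replicate 1 alone, at a mean difference of -0.109 (5.76e-04), and without replicate 1 of BA at 48 h (0.0187). By list, 15 of 15 streak genes, 14 of 15 early mesoderm genes, 12 of 13 BMP-SMAD targets, 7 of 12 WNT targets and 6 of 9 trophoblast genes were higher in BA, with 0 lower in each. Of 12 endoderm genes 6 were higher and 1 lower. Of 15 FGF-ERK targets 1, IER3, was higher and 3 lower, ETV5, DUSP4 and ETV4, the reverse of the direction of the list at 48 h. With replicate 1 alone 4 were higher and 3 lower, so that reversal depends on the libraries used. Of 12 neuroectoderm genes 5 were lower and 0 higher, and of 20 pluripotency genes 5 were lower and 1, FGF4, higher. None of the 14 proliferation genes was called.

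The spline test of E6 against E8 called 50 of 19400 genes, 32 higher and 18 lower in E6, and 663 at an unadjusted p below 0.05. With 4 degrees of freedom it called 11, and with time as a factor edgeR called 0 (414 at an unadjusted p below 0.05), so that no gene named here passes with that setting; the DESeq2 likelihood ratio test called 257. DUSP6 fell late in E6, with 409 CPM at 24 h, 274 at 36 h, 114 at 42 h and 52.6 at 48 h (mean log2 difference from E8 -0.71, adjusted p = 3.54e-04). With replicate 1 alone it was the only 1 of the 10 genes named here to pass (0.0190), the others having adjusted p from 0.106 to 1.0. ETV5 (-0.49, 0.00158), SPRY4, an ERK inhibitor gene (-0.45, 0.00753), and NFE2L3, a stress factor gene (-0.37, 6.57e-04), were lower too. FEZF1 (1.40, 0.00263) was higher in E6, at 6.93 CPM at 42 h and 35.7 CPM at 48 h, with FEZF1-AS1 (1.23, 0.00525), C6orf141 (0.66, 0.00753) and the forkhead gene FOXI3 (0.47, 0.00525). The forebrain factor OTX2 (0.76, 0.00982) reached 239 CPM in E6 at 48 h, and HMX2 was lower (-0.83, 0.0281). OTX2, C6orf141, HMX2 and SPRY4 lost their calls without a single 48 h library (adjusted p up to 0.0759, 0.0657, 0.184 and 0.0527). No marker gene was called (SOX2 0.104, NANOG 0.222), although SOX2 passed without replicate 1 of E8 at 48 h (0.0123), and SOX2 and NANOG passed by the DESeq2 likelihood ratio test (6.35e-06 and 0.00436). Of 15 FGF-ERK targets 4 were lower and 0 higher (5 adjusted over the list alone). Leaving out 1 library gave from 14 genes without replicate 2 of E8 at 48 h to 100 without replicate 1 of E6 at 48 h, and replicate 1 alone gave 4, of which 2 were shared. Without the E6 18 h and E8 24 h libraries, which stood apart from their neighbours, the count was 67. Without the E8 18 h and 36 h libraries it was 37, of which 31 were shared.

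In replicates 2 and 3 the response to BA differed from that in replicate 1. Over 551 genes that differed between BA and E6 at 36 h in the replicate 1 set, the slope of the 48 h change from t0 in replicates 2 and 3 on that in replicate 1 was 0.468 (95% bootstrap interval 0.434 to 0.50). That choice favours genes that respond strongly in the replicate 1 set. The slopes were taken after adding 1 CPM, which shrinks the changes of genes near 0 CPM. Other genes, 338 in number, differed between BA at 24 h and E6 at 48 h in replicates 2 and 3. Over these the slope was 0.574 (0.486 to 0.654) and the reverse slope 0.769. Scatter between the sets lowers both slopes, so neither gives the size of the response by itself. The first was the lower, so the summed squared changes were smaller in replicates 2 and 3, each a mean of 2 libraries. SOX2 changed by -5.63 in replicate 1 and by -0.61 in replicates 2 and 3 (log2), and EOMES by 9.78 and 5.23. In E6 at 48 h against t0 the change of EOMES also differed between the sets, by -3.61. In BA against E6 at 48 h the difference of EOMES between the sets was -1.09 ± 0.54 SE and that of SOX2 5.64 ± 0.21. The counts of genes called for BA therefore mix libraries whose measured changes differed in size.

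**Figure D4:**
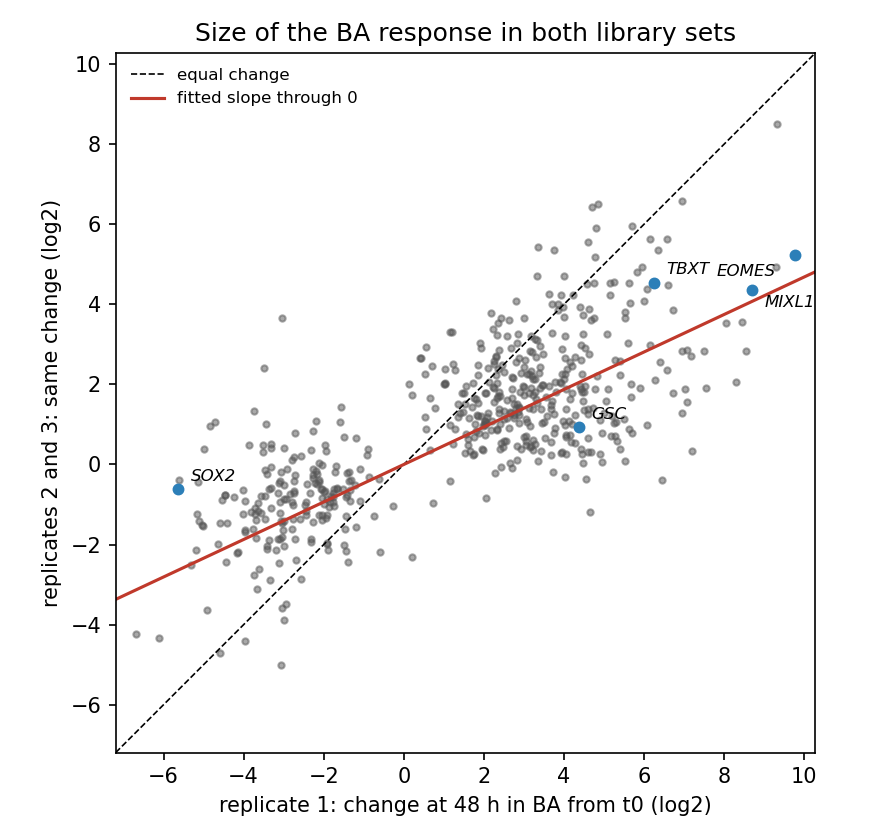
Change at 48 h in BA from t0 (log2) in replicates 2 and 3 (vertical) against that in replicate 1 (horizontal) for 551 genes chosen at 36 h, 1 point per gene. The red line has the fitted slope of 0.468 and the dashed line marks equal change.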

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

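All tests of the explanations in this part were chosen only after the result was seen. The tests of a difference between library sets, including the split into replicate 1 and replicates 2 and 3 itself, were also made after seeing the data.

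The response of BA cells differed between replicate 1 and replicates 2 and 3 by a test of that difference. In BA at 48 h against t0, SOX2 was higher in replicates 2 and 3 than replicate 1 would give, by 5.42 on the log2 scale (adjusted p = 1.79e-07), as were NANOG by 1.59 (0.00201) and POU5F1 by 1.43 (0.0338). EOMES differed by -4.70, MIXL1 by -4.37 and GSC by -3.70. EOMES and MIXL1 also shifted that way without BA, by -3.61 and -2.82 in E6 at 48 h against t0. In E8 at 48 h against t0 the shift of EOMES, -2.82 ± 0.95 SE, was not called, and MIXL1 shifted by -2.21 ± 0.40. In BA against E6 at 48 h the shift of EOMES, -1.09 ± 0.54 SE, was not called, while MIXL1 differed by -1.55 ± 0.33 and GSC by -3.53 ± 0.77. The number of genes whose response differed between the sets was 888 for BA at 24 h against t0, 4789 for BA at 48 h against t0, 2070 for E6 at 48 h against t0, 3024 for E8 at 48 h against t0 and 4042 for BA against E6 at 48 h. The test has 5 residual degrees of freedom and assumes that the lone replicate 1 library of a group varies like the others.

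The pattern weighed first is the smaller BA response in replicates 2 and 3 over genes chosen in the replicate 1 set. A difference in counting that each gene carries in every library of a set cancels within the set where levels lie well above 1 CPM. It does not cancel for genes near 0 CPM in either group, because the slopes were taken after adding 1 CPM. The slope was 0.468 over 551 genes chosen at 36 h (interval 0.434 to 0.50, and 0.763 over 149 genes in E6). It was 0.574 (0.486 to 0.654) over 338 genes chosen in replicates 2 and 3. Since genes near 0 CPM are among them, the slopes cannot decide whether a counting difference is the whole cause. The genes were first chosen in the 42 h libraries (0.431 over 556 genes). That choice was changed after the value was seen because BA at 42 h stands apart. The choice in replicates 2 and 3 was added last, and its reverse slope was 0.769. Scatter between the sets lowers both slopes, so neither gives the size of the response by itself. The forward slope was the lower, so the summed squared changes over those genes were smaller in replicates 2 and 3, each a mean of 2 libraries. An earlier stage and a smaller share of responding cells cannot be told apart: both 48 h libraries lay nearest to the 24 h point of the replicate 1 series, as a smaller response would whatever its cause, with their best correlation, which does not depend on size, at 30 h (0.792 and 0.793, against 0.751 at 48 h) and no bound set for it beforehand, and rising genes gave a median share of 26.7% and falling genes 58.3%, a ratio of 2.18 whose interval of 1.77 to 2.51 includes the bound of 2.

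In 6 genes BA and E6 moved opposite ways from t0 and also differed directly at 48 h (with the block 209). BAMBI, TES, MPP1 and the olfactory receptor gene OR52A1 were higher in BA, and PAPLN and the germ cell gene DAZL were lower. DAZL and OR52A1 stayed below 4 CPM in every group of the comparison and are outside the rule for named genes. Independent lists of the same sizes would share 22 genes that moved opposite ways from t0, before the direct difference is asked for.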

How the results depend on the processing

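The tests on replicates 2 and 3 only, with a 2-level block, without single libraries that stood apart, and the onset with replicate 1 alone were chosen only after the result was seen; all other alternatives were planned. A value counts as reversed where it changes sign and is called with either setting.

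The replicate block, which takes out the difference between replicate numbers, raised every count of genes: 1929 for BA at 24 h against t0, 2158 for BA at 48 h against 24 h, 4760 for BA against E6, 612 for E6 against E8, 5510 for E8 against t0, 6153 for BA against t0, 7553 for E6 against t0 and 3801 for BA against E8. It gave 137 transient, 977 sustained, 909 late and 209 opposite genes. All genes called without the block were called with it. Of the values of named genes 178 kept their side of the threshold and 15 passed it newly; 30 of 35 list calls held, and the 5 lost are named with their values above. It also called 8 lists newly, among them cholesterol synthesis in BA against E6 (adjusted p = 0.0269). The block changed no other call. A block of 2 levels for the library sets gave 2207, 2659, 5175, 722, 5971, 6553, 7964 and 4295 genes in the same order, and 165, 1095, 1068 and 248 genes in the classes. Replicates 2 and 3 only gave 4511, 7441, 7999, 4025, 11190, 10199, 11873 and 7228 genes and 471, 1918, 2092 and 591 in the classes. In that fit MIXL1 was lower in E6 at 48 h than at t0 (log2 change -1.15, adjusted p = 0.00408), where the fit of all libraries gave a higher value with no call. That fit leaves 2 libraries in each group, and whether they were separate cultures is not stated.

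The DESeq2 Wald test gave 821, 643, 1562, 220, 1226, 2463, 2359 and 1274 genes in the same order and 39, 450, 298 and 37 in the classes. It called 4 named values newly and lost 15. Those lost are EOMES in 4 comparisons, MIXL1 and GSC in 2 each, FGF17, GATA6-AS1, EVX1, ISL1, GATA4 and HAND1, to which DESeq2 gave no adjusted p, and HOXD1 (0.0521). DESeq2 size factors in edgeR left 191 of 193 named values and all 35 list calls on their side of the threshold. Fits of the 2 groups alone, with 4 residual degrees of freedom in place of those of 15 libraries, gave 114, 0, 76, 0, 0, 351, 3 and 47 genes by edgeR; the 3 comparisons with 0 had 1493, 946 and 2482 genes at an unadjusted p below 0.05. Of the values of named genes 81 kept their side of the threshold there and 87 lost the call, among them at 24 h TBXT (adjusted p = 0.129), EOMES (0.0668), GATA3 (0.0621) and NOTUM (0.129). Without a filter the counts were 65 for BA at 48 h against 24 h, 1 for E8 against t0 and 234 for E6 against t0, with 5 transient genes and 1 opposite gene. The HOX list in BA at 48 h against 24 h then holds more than HOXD1 and changed direction (0.386), and at 24 h it lost its call (0.0908). With at least 10 CPM in 3 libraries the counts were 465 for BA against E6, 52 for E8 against t0, 864 for BA against t0 and 334 for BA against E8, with 140 sustained genes. The neuroectoderm list in E6 against E8 then changed direction (0.802), and 6 list calls were lost: streak (0.686), endoderm (0.0947) and trophoblast (0.214) in BA at 48 h against 24 h, FGF-ERK in BA against E6 (0.0843), and pluripotency and early mesoderm in E8 against t0 (0.0947 both). For the counts under each of these settings the cause was not tested.

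Of 35 lists called by camera, 12 were called with an estimated correlation and 18 were called by fry, 17 of them also by camera. When 1 library was left out, 32 to 38 lists were called. The streak list in BA at 48 h against 24 h had adjusted p from 6.05e-05, without replicate 1 of BA at 24 h, to 0.883, without replicate 1 of BA at 48 h, where it also changed direction. The cause was not tested.

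Leaving out 1 library at a time gave these ranges: 84 to 206 genes for BA at 24 h against t0, 3 to 175 for BA at 48 h against 24 h, 257 to 670 for BA against E6, 2 to 56 for E6 against E8, 0 to 624 for E8 against t0, 376 to 1443 for BA against t0, 48 to 1575 for E6 against t0 and 193 to 504 for BA against E8. The 0 for E8 against t0 came without replicate 2 or 3 of either group, by edgeR, with 1938 to 2270 genes at an unadjusted p below 0.05. The classes ranged over 1 to 11 transient, 49 to 289 sustained, 1 to 112 late and 1 to 22 opposite genes. Of the values of named genes 855 kept their side of the threshold and 303 lost the call. The highest counts for 48 h groups came without a replicate 1 library.

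The time course of E6 against E8 was not stable. It called 50 genes, 11 with 4 degrees of freedom, 0 by edgeR with time as a factor (414 at an unadjusted p below 0.05), 257 by the DESeq2 likelihood ratio test, 4 with replicate 1 alone and 14 to 100 with 1 library left out. BA against E6 called 5129 genes with replicate 1 alone and 2028 to 2832 with 1 library left out, and stayed within 1.5 times of 2451 under the other settings. With replicate 1 alone NANOG changed sign and was called (-0.109, adjusted p = 5.76e-04), and SOX17 had its onset at 24 h. Among the 11 marker genes no onset moved under another fold, minimum, scaling or t0 library. The onsets of other genes were not tried with these settings. The cause of the changes in this paragraph was not tested.

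Depth limits the low genes. Genes at 0 counts in a group, such as NOTUM at t0, have a fold change that rests on the fit's floor, and calls of genes below 1 CPM in both groups rest on few reads.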

Other observations

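Tests of the explanations for the low epithelial genes, for the E6 18 h library and for streak transcripts in E6 and E8 were chosen only after the result was seen; the counts over other splits of the libraries were planned.

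Along the BA series, BMP feedback came on at once and mesoderm genes in steps. The BMP-SMAD target median had risen by 2.57 on the log2 scale at 6 h in BA and by 4.06 at 24 h, and stood at 3.19 at 36 h, 1.72 at 42 h, in a library that stands apart (below), and 2.62 at 48 h. ID1, ID4, SMAD6, BAMBI, MSX2 and NOG all met the onset rule at 6 h. In the mesoderm list TBX3, of heart and limb, met it at 12 h, PDGFRA, HAND1 and FOXC1 at 30 h, and MESP2, TBX6 and DLL3 at 36 h. The neuroectoderm median had dropped by 1.05 at 18 h in BA. These members were picked after their values were seen. The medians are those of replicate 1 alone, also at 24 and 48 h, where other replicates exist. The onsets used the mean of 3 replicates at t0, 24 and 48 h and single libraries elsewhere.

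Streak transcripts were detected at low level outside BA. In E6 at 24 h EOMES stood at 4.50 CPM, MIXL1 at 5.31 and PCAT14 at 26.4, and in E8 at 12 h PCAT14 stood at 25.7 CPM. Reads or cells from BA cultures and streak genes switched on without a BMP response were set against each other. If BA reads were mixed in, 7 BMP and trophoblast genes would stand near the level that 15 streak genes predict, and their ratio to it was -0.00959 (interval -0.483 to 0.412). By the bounds first written, that argues against mixed-in reads and for streak genes alone. The verdict was withdrawn after the value was seen, because all 7 genes lie near the floor in the controls, at a mean of at most 0.773 CPM. Against the mean of the 3 t0 libraries the ratio is 0.325, on the same side of the bound of 0.5. A first ground for withdrawing it, a predicted signal below the spread at t0, was checked and was not met (2.94 against an SD of 0.857 CPM), so the 2 explanations cannot be told apart on a ground set afterwards.

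In the E8 18 h, E8 36 h and BA 42 h libraries, epithelial genes lay below the neighbouring time points, with medians of -1.47, -1.37 and -1.41 (log2). The cadherin gene CDH1 went from 125 CPM in E8 at 12 h to 18.6 at 18 h and back to 98.4 at 24 h, and from 123 at 30 h to 25.1 at 36 h and 138 at 42 h; other genes, also chosen after their values were seen, moved alike at both times, such as ZFP42 (97.4, 10.9 and 90.7, then 92.5, 12.3 and 94.3 CPM) and GBX2 (28.4, 92.0 and 49.4, then 31.4, 93.8 and 43.3). A bias of length or GC content would leave the medians near 0 once its trend is taken out, and the highest of the 3 was then -1.27. Cells that are no longer pluripotent taking most of the culture would lower the pluripotency list too, whose lower median in the E8 libraries was -0.303 although its member ZFP42 fell. The design names no biological explanation, and a different culture or clone behind these libraries is open and untested; the deviations of the 2 E8 libraries correlated at r = 0.788, and with BA at 42 h at 0.418 and 0.499.

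The E6 18 h library stood apart from its neighbours. Its deviation followed transcript length over 11566 genes (Spearman -0.689), and so did that of E8 at 24 h (-0.628), against at most 0.229 in size in libraries that are neither of these nor next to them. A length bias may therefore be a candidate explanation, and it would hold for both libraries. With the length and GC trend taken out it correlated best with the E8 24 h library (0.805), and next with E6 at 12 h (0.375). A wrong label and a property shared by these 2 libraries cannot be told apart, since each is a single library. No biological explanation was tested.

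Other splits of the 6 libraries of each pair of groups number 10 with the real one, too few for a share under 0.05. The real split gave 339 genes for BA at 24 h against t0, 98 for BA at 48 h against 24 h, 759 for BA against E6, 31 for E6 against E8, 30 for E8 against t0, 1373 for BA against t0, 836 for E6 against t0 and 526 for BA against E8. The real split was the only 1 of 10 to give as many in each, and the highest other split gave 0, except for 2 in BA against E6. Among the 4 splits that part all pairs, with the replicate block, the real split and the highest other gave 1929 and 2, 2158 and 46, 4760 and 40, 612 and 2, 5510 and 30, 6153 and 225, 7553 and 21, and 3801 and 2 genes in that order. For the time course of E6 against E8, 1 of 50 splits, the real one, gave as many as 50 genes (highest other 7), a share below 0.05. For BA against E6, 2 of 50 gave as many as 2451, also below 0.05. The other gave 8604 genes and put all 6 libraries of replicates 2 and 3 in one group, so it follows the library sets; with replicate 1 alone the real count was 5129. Further splits gave 1204, 899 and 309 genes, so mixed groups of these libraries also give many calls.

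Some genes appeared in 1 library set only. There were 50 genes with at least 5 CPM in every library of replicates 2 and 3 and below 0.5 CPM in all others, 26 of them processed pseudogenes, 1 a transcribed processed pseudogene and 23 without a type in the annotation. The reverse held for 2 protein-coding genes, HEPH, of iron transport, and C17orf51, chosen after their values were seen.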
